A study of Mus musculus with 60 samples.

How the data were processed

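Gene expression was measured in pancreatic islets of pIns-MYCERTAM mice on 60 Affymetrix arrays. In these mice an insulin promoter drives a fusion of MYC with a modified oestrogen receptor part in beta cells, and the fusion protein becomes active when 4-hydroxytamoxifen is given. Male CBA-C57BL/6 mice received 1 mg of 4-hydroxytamoxifen per day in the abdominal cavity, or peanut oil. They also received exendin-4, a peptide agonist of the GLP-1 receptor also called exenatide, at 50 µg/kg under the skin, or water, from 2 days before. The age is given as 8 to 12 weeks in one label and as an adult age in months in another, and the difference was not resolved. Islets were cut out by laser from frozen pancreas sections of 15 µm, and 6 µg of RNA were labelled per array, per the labels' protocols. The labels call the 3 arrays of each group biological replicates and do not tie an array to a named animal.

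The deposited values are log2 expression values of 45101 probe sets. The submitters' processing notes name MAS5 and GCRMA with no role or version, and further upstream steps are not given in the sources used here. The log base is not stated and was inferred from the deposited values, which ran from -12.3 to 12.8. Natural logs of 16-bit intensities reach 11.1 at most, so base 2 was taken. In the deposited table the median of every probe set over the 60 arrays was 0 (100% of probe sets, tolerance 1.0e-04), against 9.27% of probe sets with a median of 0 over the 52 arrays kept. Each value is thus the deviation of a probe set from its own median, and absolute levels cannot be read from the table.

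The loss of the level changed 1 planned step. The plan was to leave out probe sets with a low mean and to let the probe set with the highest mean stand for its gene. Neither can be computed from centred values, so the interquartile range over the arrays in the fit took the place of the mean. Probe sets at or above the 40th percentile of that range (0.101 log2 units) were kept, and the one with the widest range stood for its gene. A filter on spread leaves out genes that hardly vary, whatever their level, so an expressed gene can be missing. The array annotation gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160, and 64 control probe sets were left out. Of these symbols 34741 were matched by Entrez number to the RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 needed updating. Probe sets with no symbol or several were not tested. There were 27022 probe sets past the filter, and 13176 of the 18193 named genes were tested. The number of arrays limits the precision, and limits from background were not measured.

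The submitters left out 8 of the 60 arrays for poor reproducibility, and the 52 others entered the fit. Of the 20 groups, 12 held 3 arrays and 8 held 2. The log2 values were used as deposited, without further scaling. One linear model with 20 group means was fitted with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading, and moderated with eBayes (32 residual and 2.75 prior degrees of freedom). Contrasts were taken at each of the 5 times and as the mean of the 5 times with equal weight. They covered the MYC effect with water, the MYC effect with exendin-4, the exendin-4 effect without and with MYC, and the interaction of both. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. By chance alone, a share of 0.05 of the genes would have an unadjusted p under 0.05. Every adjusted p of a gene below is from this limma model. Values with ± are log2 differences with their standard error (SE). Changes over time were tested with limma's moderated F test. Figures were drawn with matplotlib 3.10.9.

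There were 26 gene lists, covering endocrine and other cell types, secretion, MYC-related growth, the cell cycle, stress, signalling and metabolism, with 435 of 521 members tested. They were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. At the preset value, random splits of the arrays gave a median of 4 to 6 of the 26 lists past the threshold. A call at the preset value is thus weak evidence on its own, and its p are likely too small. The mean of each list per array was also tested with limma. That test, the F test on the mean of both injections and the contrast of 4, 8 and 32 h against 16 and 72 h were added after seeing the data. Camera compares the mean statistic of a list with that of the other genes, so for lists not past the threshold its direction and the sign of the list mean can differ. For the text, the 8 genes with the largest rise and the 8 with the largest fall past the threshold and of 1 sign at all 5 times were named in each averaged contrast. Up to 3 members past the threshold were named per list, with 20 fixed genes, the 10 smallest p of each F test, and the 5 smallest p where fewer than 5 genes passed. Of the genes chosen in this way, 1 is not reported here. Groups, tests, lists, naming rules and the first set of alternatives were fixed before the data were examined.

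The alternatives were all 60 arrays, no filter, quantile normalization, the replicate number as a block, the mean over probe sets of a gene, only the arrays compared in the fit, and each array left out in turn. At single times the fit of the arrays compared held all 4 treatments of that time. Alternatives chosen after seeing the data were a filter at the 60th percentile, limma's array weights, leaving out the 2 kept arrays of widest spread (MycOFF exendin-4 16 h replicate 3 and 72 h replicate 2) and the acinar marker mean as a covariate, with immune and alpha cell marker means as covariates in the contrast of times. The steps were tested on simulated data with changed genes of known size among the 13176. For the MYC effect with water averaged over times, changes of 0.5, 1 and 2 log2 units were recovered in 32.8%, 62.7% and 93.9% of cases, with 5 false calls among 131. For the 4 h contrast these shares were 1.49%, 10.4% and 53.0%, with 1 false call among 44. In the simulated average, raising the 13 glycolysis members by 1 log2 unit gave a call for that list and 3 calls among the 26 lists. The simulated genes varied independently of each other, each with the same spread in all arrays. These shares and false calls need not hold for the real arrays, whose standard deviations ran from 0.284 to 0.949.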

Results

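The series asked how exendin-4 acts on islets in which MYC has been switched on, and how islet expression moves over time. Islets were taken at 4, 8, 16, 32 and 72 h in 4 treatments: 4-hydroxytamoxifen with water (MycON water), 4-hydroxytamoxifen with exendin-4, peanut oil with water (MycOFF water) and peanut oil with exendin-4. Exendin-4 or water began 2 days before, so these hours are not the time since exendin-4 began. All MycON mice received 4-hydroxytamoxifen, all MycOFF mice peanut oil, and no group without the fusion received the drug. In every comparison below, an effect of 4-hydroxytamoxifen apart from MYC can therefore not be told apart from the MYC effect. Of the 60 arrays, 52 were used: 13 MycON water, 12 MycOFF water, 12 MycON exendin-4 and 15 MycOFF exendin-4, with 2 or 3 arrays per time. The values are log2 deviations of each probe set from its median over the 60 arrays. Their standard deviation within an array ran from 0.284 to 0.949 in the arrays kept and from 0.969 to 1.40 in the 8 left out. Between 2 arrays of 1 group the differences of single genes had a standard deviation of 0.555 to 1.42 log2 units over 44 pairs.

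With water, genes of the machinery that licenses and runs DNA replication were higher in MycON than in MycOFF islets. Cdt1, which loads the replicative helicase onto origins, was 14.6-fold higher, a difference of 3.86 ± 0.44 (SE; 13 against 12 arrays; adjusted p = 5.9e-07). The helicase subunits Mcm5, Mcm6 and Mcm3 rose by 3.09 ± 0.50, 2.58 ± 0.42 and 2.53 ± 0.40, and the chromatin remodelling helicase Hells by 2.52 ± 0.37. Psat1, an enzyme of serine synthesis, rose by 2.86 ± 0.31, the tetraspanin Tspan4 by 2.72 ± 0.26 (adjusted p = 8.4e-09) and Lgals3, which encodes galectin-3, by 2.70 ± 0.59. These 8 genes had positive values at all 5 times. The genes that fell included Cplx2, which encodes a regulator of vesicle fusion (-2.06 ± 0.55), and Ucn3, a marker of mature beta cells (-1.59 ± 0.48, adjusted p = 0.0423). Rab37, which encodes a GTPase of secretory vesicles, fell by 1.59 ± 0.31 and Pdx1, a transcription factor that maintains beta cells, by 0.90 ± 0.19 (adjusted p = 0.00326). Prr15, Rian, Kctd12b, Slc6a19 and Slc22a23 fell by between 1.76 and 1.71 log2 units. In limma, 737 of 13176 genes passed, 519 higher and 218 lower, and 335 of them by at least 2-fold. The count was 175 with all 60 arrays, where 29 of the 37 named genes past the threshold lost their call (Cdt1, Psat1 and Tspan4 did not), and quantile normalization gave 1175, with 758 higher and 417 lower. Calls of Ucn3, Slc6a19, Shmt2 and Eif4e ended without 1 of 17, 15, 19 and 26 arrays (adjusted p up to 0.157, 0.0959, 0.132 and 0.542), and other probe sets of Cdt1, Hells, Mcm6 and Rian lay as near to 0 as -0.08, -0.06, 0.06 and -0.08. Quantile normalization ended the calls of Rian, Eif4e and Ppat (adjusted p = 0.187, 0.292 and 0.0824). The replicate block ended 7 calls of named genes: Ucn3, Slc6a19, Rph3al, Mthfd1l, Shmt2, Foxo1 and Cyc1 (adjusted p from 0.0502 to 0.0737). Other probe sets of Bop1 and Top2a, named below, were at 0.16 and 0.13.

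**Figure D1:**
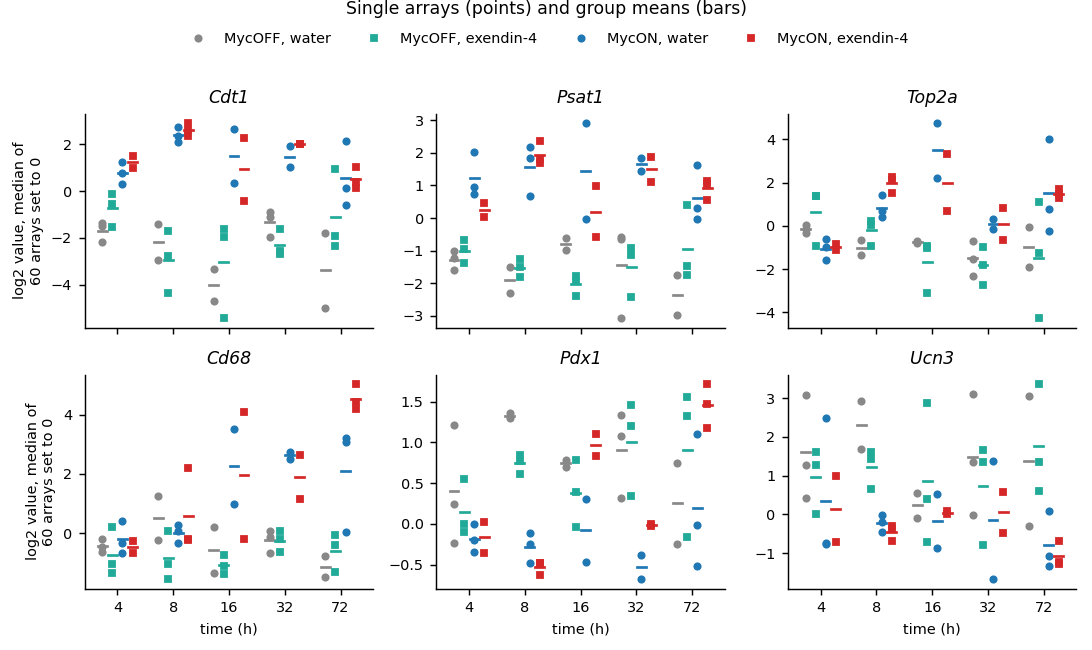
Log2 values of 6 genes in the 52 arrays used (vertical axis, median of 60 arrays set to 0) by time in h (horizontal axis, steps not to scale), with points for arrays, bars for group means and colours for the 4 treatments. The MYC effect with water averaged 3.86 for Cdt1, 2.86 for Psat1, 1.85 for Top2a, 1.73 for Cd68, -0.90 for Pdx1 and -1.59 for Ucn3.

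The gene groups that rose with MYC in water were those of proliferation and growth. Of 24 tested DNA replication genes 18 rose over all genes and 21 adjusted over the list alone (camera adjusted p = 2.7e-28; adjusted p = 0.00747 with an estimated correlation), and their mean rose by 1.65 ± 0.23 (adjusted p = 4.5e-07). Of 22 mitosis genes 13 rose, 21 adjusted over the list alone, among them Cdca8 (2.10), a subunit of the chromosomal passenger complex, the cyclin gene Ccna2 (1.88) and the topoisomerase gene Top2a (1.85). Of 29 ribosome biogenesis genes 10 rose, 12 adjusted over the list alone, such as Nhp2 (1.64), Bop1 (1.57) and Nop16 (1.39). Of 27 known MYC targets 5 rose, 9 adjusted over the list alone, with Eif4e, the cap-binding translation factor, at 1.33, Mthfd1l at 1.13 and the purine synthesis gene Ppat at 0.97. Of 13 one-carbon and serine genes 3 rose, 4 adjusted over the list alone: Psat1, Shmt2 (1.37) and Phgdh (0.87). Camera adjusted p were 2.8e-18 for mitosis, 7.9e-13 for ribosome biogenesis, 4.3e-09 for MYC targets and 7.5e-05 for one-carbon genes. With an estimated correlation these 4 calls were lost (adjusted p = 0.0564 for each), while their list means passed, at 1.27 ± 0.29 (0.00107), 0.76 ± 0.19 (0.00267), 0.61 ± 0.16 (0.00323) and 0.68 ± 0.18 (0.00323).

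Camera placed 6 further lists past the threshold with water, and none of these 6 passed with an estimated correlation or as a list mean. The beta cell identity list was lower (adjusted p = 6.8e-04; adjusted p = 0.457 with an estimated correlation), with 2 of 18 members lower over all genes and 2 adjusted over the list alone, Pdx1 and Ucn3, and a mean of -0.44 ± 0.22. In the secretory granule list (0.00527; adjusted p = 0.406 with an estimated correlation) 1 of 23 fell by either count, Rph3al at -0.91. The glycolysis list (0.00557; adjusted p = 0.412 with an estimated correlation) held Slc16a1, the lactate and pyruvate transporter, at 2.23 ± 0.31, and Pgam1 at 0.70, with 2 of 13 higher and 3 adjusted over the list alone. In oxidative phosphorylation (0.00615; adjusted p = 0.724 with an estimated correlation) 1 of 22 rose by either count, Cyc1 at 0.67. Acinar markers, the enzymes of the exocrine tissue around islets, were shifted up with 0 of 20 past the threshold by either count, and 19 of 20 were above 0 (0.0333; adjusted p = 0.759 with an estimated correlation; mean 0.45 ± 0.40). Immune markers (0.0445; adjusted p = 0.724 with an estimated correlation) had 1 of 15 higher by either count, Cd68 of macrophage lysosomes at 1.73. Of lists not past the threshold, endothelial markers held Kdr (-1.05), cAMP and CREB targets Rasd1 (-0.65), GLP-1 receptor signalling Foxo1 (-0.56), the genes silenced in beta cells Slc16a1, and the circadian clock Hlf (1.09), each as the 1 member past the threshold. Camera adjusted p for these 5 were 0.0926, 0.667, 0.205, 0.205 and 0.867. Over all genes, 0 members passed among alpha, delta and PP, duct and stromal markers, p53 and apoptosis, the unfolded protein response, ribosomal proteins, inflammation, heat shock and cholesterol synthesis (camera adjusted p from 0.0781 to 0.925), and adjusted over the list alone 1 did, in cholesterol synthesis.

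The MYC effect on replication and mitosis genes differed between times. Averaged over both injections, the replication list mean was 0.50 ± 0.34 at 4 h and rose by 2.51 ± 0.34 at 8 h (adjusted p = 3.2e-07), 2.26 at 16 h, 1.63 at 32 h and 1.26 at 72 h. Arrays of 1 group differed widely at 16 and 72 h. Replication means of single MycON arrays at 16 h were 2.90 and 0.90 with water and 0.33 and 1.94 with exendin-4. At 72 h they were -0.23, 0.07 and 2.40 with water and 0.39, 0.29 and 0.96 with exendin-4. The mitosis mean was -0.46 ± 0.43 at 4 h, 1.13 ± 0.43 at 8 h (adjusted p = 0.0675), 2.95 ± 0.48 at 16 h (adjusted p = 9.6e-06), 0.57 ± 0.45 at 32 h and 1.84 ± 0.43 at 72 h (adjusted p = 0.00178). Mitosis means of single MycON arrays at 16 h were 4.39 and 2.11 with water and 0.75 and 2.92 with exendin-4. At 72 h they were 0.60, 0.75 and 3.30 with water and 1.17, 1.85 and 1.90 with exendin-4. Ribosome biogenesis rose by 0.99 at 8 h and 1.24 at 32 h and stood at 0.00 ± 0.28 at 72 h. The change over time passed for mitosis (adjusted p = 0.00231) and replication (adjusted p = 0.0231) and not for immune markers (0.0723) or ribosome biogenesis (0.217). Among single genes 209 changed over time on the mean of both injections (1723 at unadjusted p under 0.05), against 18 with all 60 arrays, 84 with the replicate block, 375 with quantile normalization, 327 with the mean over probe sets and 380 with array weights. The smallest p belonged to Dctd, a deaminase of pyrimidine nucleotides, with 1.90, 2.04, 0.37, 2.06 and -0.34 from 4 to 72 h (adjusted p = 5.9e-05). With water alone Dctd stood at 2.08, 1.69, 1.42, 2.19 and -0.41, so a low value at 16 h was not shown with water. In the mean of both injections Polr3g, a subunit of RNA polymerase III, Fig4, Ak4 and Tmem158 followed the same order of high and low times as Dctd. There Cdkn2d, which encodes an inhibitor of CDK4 and CDK6, stood at 2.87 at 16 h and between -0.57 and 0.14 at the other times. Cd36, a scavenger receptor, and Slc37a2 were highest at 72 h (3.97 and 2.20), Ccbe1 was at 1.56 at 32 h, and Smpdl3b was at 0.72 at 72 h and between 1.85 and 3.54 before. With water alone only Ccdc137, Rita1 and Cdkn2d passed (adjusted p = 0.0445 for each, 721 genes at unadjusted p under 0.05), a count that ran from 0 to 31 without 1 array (31 without MycON water 16 h replicate 2).

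**Figure D2:**
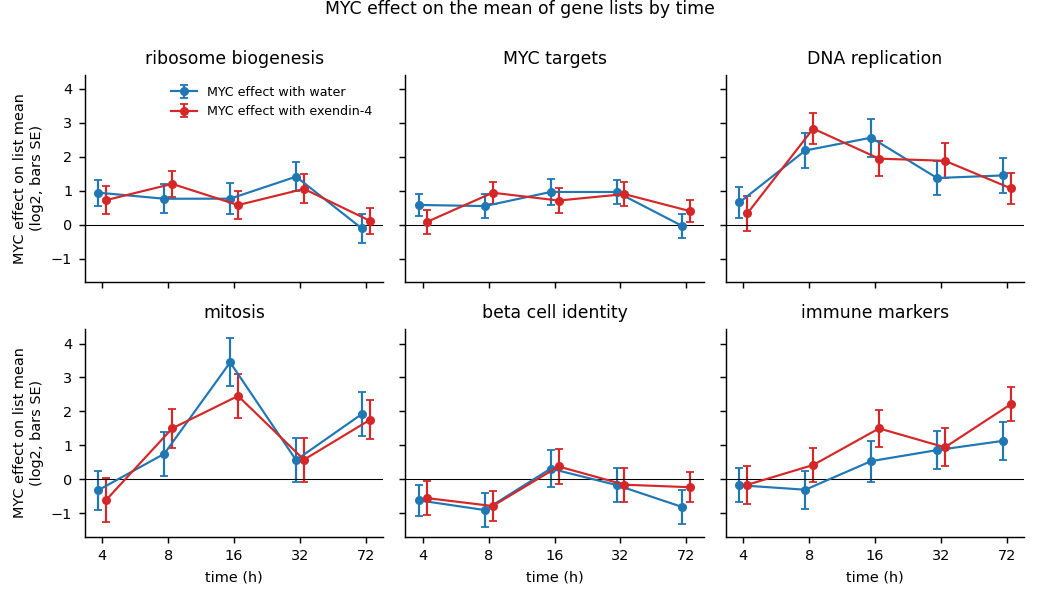
MYC effect on the mean of 6 gene lists (vertical axis, log2; bars are SE) by time in h (horizontal axis, steps not to scale), with water and with exendin-4. Averaged over both injections, replication stood at 2.51 at 8 h, mitosis at 2.95 at 16 h and immune markers at 1.67 at 72 h.

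**Figure D3:**
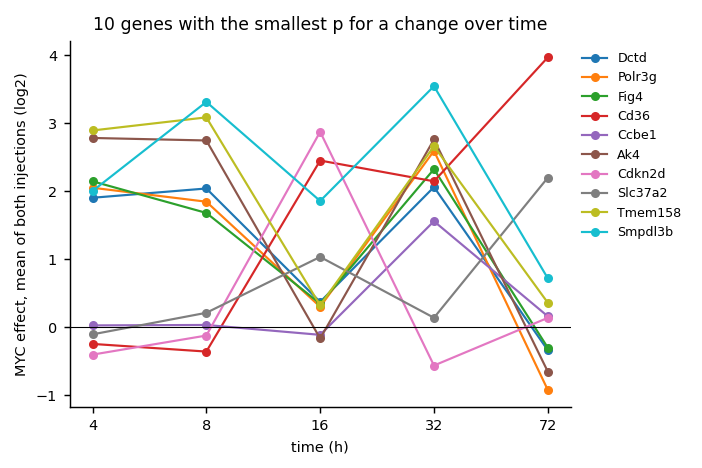
MYC effect (vertical axis, log2, mean of both injections) by time in h (horizontal axis, steps not to scale) of the 10 genes with the smallest p for a change over time, 1 line per gene and no error bars. Ak4 stood at 2.78, 2.74 and 2.76 at 4, 8 and 32 h, and at -0.17 and -0.65 at 16 and 72 h.

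At single times the MYC effect with water took in 99, 33, 45, 63 and 3 genes from 4 to 72 h, and with exendin-4 it took in 25, 179, 11, 43 and 132. Each of these 10 counts rests on 2 or 3 arrays per group and moved by over 1.5 times without some arrays, so no order of times is read from them. The count at 72 h with water was 125 without MycOFF water 72 h replicate 1. The count at 72 h with exendin-4 was 50 without MycON exendin-4 replicate 3, and 65, 238 and 224 without MycOFF exendin-4 replicates 1, 2 and 3 of that time. At 8 h with exendin-4 it was 57 without MycOFF exendin-4 8 h replicate 1 and 257 without replicate 3.

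**Figure D4:**
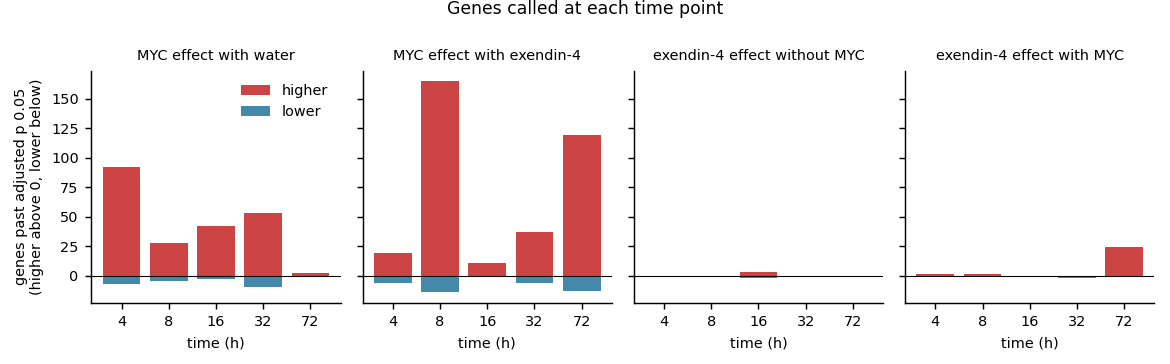
Number of genes past an adjusted p of 0.05 (vertical axis, higher above 0 and lower below 0) by time in h (horizontal axis, steps not to scale) in 4 comparisons. The MYC effect took in up to 99 genes at 1 time with water and 179 with exendin-4, and the exendin-4 effect up to 5 without MYC and 25 with MYC.

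With exendin-4, replication and mitosis genes were again higher in MycON than in MycOFF islets. Cdt1 rose by 3.48 ± 0.43 (12 against 15 arrays; adjusted p = 2.5e-06) and Cdca5, which encodes a protein of sister chromatid cohesion, by 3.25 ± 0.61. Mcm5 rose by 3.08, Trip13 by 3.08, Tspan4 by 3.01 ± 0.25 (adjusted p = 2.3e-10), Lgals3 by 2.96 and Mcm6 by 2.83, each with positive values at all 5 times. Of the immune marker list, Cd68 rose by 2.40 ± 0.38 (adjusted p = 1.0e-04), the lysozyme gene Lyz2 by 1.88 ± 0.44 and the complement gene C1qc by 1.69 ± 0.31. The 8 largest falls among genes with 1 sign at all 5 times were those of Hs3st6 (-1.84 ± 0.33), A330076H08Rik (-1.70), Rbm5 (-1.55), Rab37 (-1.44), Zfp783 (-1.43), Chac1 (-1.43), Dleu2 (-1.37) and Scnn1b (-1.29). Ddit3, which encodes the stress factor CHOP, fell by 1.14 ± 0.20 and Xbp1, a driver of the unfolded protein response, by 0.93 ± 0.20. In limma 763 genes passed, 601 higher and 162 lower (314 by at least 2-fold), with 508 without MycON exendin-4 4 h replicate 2, and quantile normalization gave 725 higher and 343 lower. Xbp1 was at 0.22 with all 60 arrays (adjusted p = 0.818), where calls of 8 others of the 41 named genes past the threshold ended, Rbm5 and Eif4e among them, and the mean over probe sets ended those of Xbp1 and Dleu2 (adjusted p = 0.117 and 0.0522). A fit of only the arrays compared ended 8 calls: Chac1, Bop1, Hspd1, Id2, Pgk1, Ndufa4, Hlf and Odc1 (adjusted p from 0.0511 to 0.125). Second probe sets of Ddit3, Bop1, Top2a and Trip13 lay at -0.13, 0.01, 0.04 and 0.24. Other probe sets of Cdt1, Mcm6, Dleu2 and Rbm5 lay at -0.10, 0.00, -0.03 and -0.10, and calls of Chac1, Odc1, Rbm5 and Hspd1 ended without 1 of 33, 14, 13 and 13 arrays.

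With MYC under exendin-4, 18 of 24 replication genes rose, 21 adjusted over the list alone (camera adjusted p = 1.5e-25; adjusted p = 0.0133 with an estimated correlation; mean 1.61 ± 0.22). Of 22 mitosis genes 10 rose, 17 adjusted over the list alone (5.4e-13; adjusted p = 0.157 with an estimated correlation; mean 1.14 ± 0.28), such as Cdca8 (2.60), Ccna2 (1.93) and Top2a (1.83). Of 29 ribosome biogenesis genes 10 rose, 14 adjusted over the list alone, with Nhp2 at 2.02, Nop16 at 1.47 and Bop1 at 1.40 (3.4e-11; adjusted p = 0.135 with an estimated correlation; mean 0.74 ± 0.18). Of 27 MYC targets 7 rose, 10 adjusted over the list alone, with Eif4e at 1.40, the chaperonin gene Hspd1 at 1.00 and Id2 at 0.99 (4.3e-08; adjusted p = 0.133 with an estimated correlation; mean 0.61 ± 0.15). Of 15 immune markers 4 rose, 8 adjusted over the list alone (1.3e-07; adjusted p = 0.157 with an estimated correlation; mean 0.98 ± 0.24). One-carbon genes had 2 of 13 higher and 4 adjusted over the list alone, Psat1 at 2.36 and Shmt1 at 1.37 (0.00314; adjusted p = 0.203 with an estimated correlation; mean 0.55 ± 0.17). Glycolysis had 3 of 13 higher by either count, Slc16a1 at 2.37, Pgk1 at 0.78 and Pgam1 at 0.66 (0.00214; adjusted p = 0.302 with an estimated correlation; mean 0.49 ± 0.19). These 7 list means passed (adjusted p from 2.9e-07 to 0.0484).

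Another 5 lists passed camera under exendin-4 and not as list means. Oxidative phosphorylation was higher (6.2e-04; adjusted p = 0.495 with an estimated correlation), with 2 of 22 members past the threshold and 3 adjusted over the list alone, Ndufa4 (0.88) and Cyc1 (0.73) among them. Genes normally silenced in beta cells were higher (0.0252; adjusted p = 0.486 with an estimated correlation), with Slc16a1 and Arhgdib (1.03) as the 2 of 19 past the threshold by either count. Beta cell identity (0.0171; adjusted p = 0.495 with an estimated correlation) and secretory granule genes (0.0252; adjusted p = 0.486 with an estimated correlation) were lower with 0 of 18 and 0 of 23 members past the threshold by either count. The unfolded protein response list was lower (0.0264; adjusted p = 0.495 with an estimated correlation), with 4 of 22 lower by either count, Chac1, Ddit3 and Xbp1 among them. The cell cycle inhibitor gene Cdkn2a rose by 0.81 ± 0.18 (adjusted p = 0.00473), the 1 member of the p53 and apoptosis list past the threshold over all genes. Adjusted over the list alone that list had 2 higher and 1 lower of 20, inflammation 2 higher and 1 lower of 14 against 0 over all genes, and the circadian clock Hlf (0.80) by either count. The remaining 11 lists had 0 members past the threshold by either count, and the camera adjusted p of all 14 lists not past ranged from 0.141 to 0.968.

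At 72 h with exendin-4 the immune marker mean rose by 2.21 ± 0.50 with MYC (adjusted p = 0.00197; 3 against 3 arrays), and 5 of 15 members rose, 9 adjusted over the list alone. The immune means of the 3 MycON exendin-4 arrays were 2.12, 1.82 and 2.59, and those of the 3 MycOFF exendin-4 arrays -0.11, 0.28 and -0.27. The MycON water arrays of that time stood at 1.51, 1.21 and -0.12 and the MycOFF water arrays at 0.13 and -0.66. Averaged over both injections the mean rose by 1.67 ± 0.37 at 72 h (adjusted p = 0.00177). With water alone it stood at 1.13 ± 0.55 (adjusted p = 0.419), and the interaction at 72 h was 1.08 ± 0.74 (adjusted p = 0.889). Stromal markers stood at 1.33 ± 0.54 (adjusted p = 0.0965) in the MYC effect at 72 h with exendin-4, with 1 of 12 members higher and 5 adjusted over the list alone. The stromal means were 1.47, 1.21 and 2.87 in the MycON exendin-4 arrays and -0.24, 2.16 and -0.39 in the MycOFF exendin-4 arrays. Alpha cell marker means in these arrays were 0.81, 0.65 and 1.55 against -0.24, 0.43 and 0.10. Delta and PP marker means were 1.04, 0.20 and 1.49 against 0.20, 0.10 and 0.40. Over both injections at 72 h, alpha cell markers rose by 0.72 ± 0.25 (limma adjusted p = 0.0432), and delta and PP markers stood at 0.34 ± 0.35.

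The MYC effects with water and with exendin-4 share no arrays and were correlated. Across the 13176 genes their correlation was 0.785 (Spearman 0.671), where genes are not independent replicates. Higher in both were 364 genes, against 23.7 for independent lists, and lower in both were 76, against 2.68. Both effects come from 1 fit with 1 variance estimate per gene, so the counts for independent lists may be too low. Of the genes past the threshold in both, 0 had opposite directions. Genes past the threshold in both include Cdt1, Mcm5, Mcm6, Tspan4, Lgals3, Psat1 and Rab37.

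Exendin-4 without MYC moved few genes. Hdac9, a class II histone deacetylase gene, fell by 2.79 ± 0.26 (15 against 12 arrays; adjusted p = 1.3e-08), Cited2, a co-regulator of transcription, by 2.15 ± 0.32 and the homeobox gene Six4 by 1.39 ± 0.19. Ttc30b (-2.26), Filip1 (-1.61), Asb15 (-1.57), Zdhhc22 (-1.36) and Dyrk2 (-1.13) fell as well. Arhgef3, which encodes a guanine nucleotide exchange factor, rose by 1.77 ± 0.29, Lrrc10b by 1.65 ± 0.25, the signalling ligand gene Wnt4 by 1.48 ± 0.33, and the kinase gene Plk3 was 2.29-fold higher (adjusted p = 0.00772). Ddit3 (0.90 ± 0.20, adjusted p = 0.0416, another probe set at 0.12) and Zbtb16 (0.87, another probe set at 0.16) rose, and Rasd1 fell by 0.65 ± 0.11. Each of these except Rasd1 was selected for 1 sign at all 5 times. In limma 30 genes passed, 8 higher and 22 lower (1009 at unadjusted p under 0.05), against 8 with all 60 arrays, 51 with quantile normalization, 17 without the filter, 13 with the replicate block, 49 with the mean over probe sets and 11 with only the arrays compared. The count was 18, 19, 18, 16 and 19 without MycOFF exendin-4 4 h replicate 2, 8 h replicate 2, 32 h replicates 1 and 3 and 72 h replicate 2, and 14, 16, 11 and 14 without MycOFF water 8 h replicates 1 and 3, 16 h replicate 2 and 32 h replicate 3. Calls of Ddit3, Dyrk2, Wnt4, Zbtb16 and Zdhhc22 ended without 1 of 23, 17, 14, 12 and 10 arrays, and other probe sets of Hdac9, Cited2 and Dyrk2 were at 0.02, -0.07 and -0.06. Of the 15 named genes past the threshold, 10 lost their call with all 60 arrays, Plk3 (adjusted p = 0.0607), Six4 (0.684) and Filip1 (0.577) among them, 9 with only the arrays compared and 6 with the replicate block.

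Targets of cAMP and CREB, which act below the GLP-1 receptor, were the 1 list of 26 past camera without MYC (adjusted p = 0.00597; adjusted p = 0.186 with an estimated correlation), and no list mean passed. Of 19 members 0 rose and Rasd1 fell over all genes, while 3 were higher and 1 lower adjusted over the list alone. Its members with the largest positive values were Crem (1.24, adjusted p = 0.0779), Rgs2 (1.19) and Egr1 (0.96), and the list mean was 0.33 ± 0.11 (adjusted p = 0.112). The unfolded protein response had 1 of 22 higher over all genes, Ddit3, and 2 adjusted over the list alone. The other 24 lists had 0 members past the threshold over all genes and camera adjusted p from 0.0609 to 0.947. Adjusted over the list alone, 3 beta cell identity, 2 heat shock, 1 delta and PP and 1 cholesterol synthesis gene were lower and 2 clock genes higher. The count of lists past camera was 0 without MycOFF water 16 h replicate 3, between 1 and 3 without any other array, and 5 with all 60 arrays. At single times the exendin-4 effect without MYC took in 1, 0, 5, 0 and 1 genes in limma (898, 383, 648, 289 and 784 at unadjusted p under 0.05). Without 1 array these counts ran from 0 to 3, 0 to 8 (MycOFF exendin-4 8 h replicate 3), 2 to 23 (MycOFF exendin-4 and MycOFF water 16 h replicate 3), 0 to 0 and 0 to 112 (MycOFF water 72 h replicate 1).

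**Figure D5:**
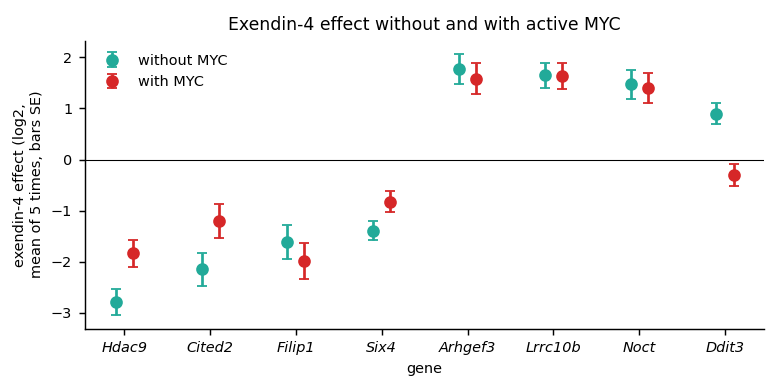
Exendin-4 effect (vertical axis, log2, mean of 5 times; bars are SE) on 8 genes (horizontal axis) without and with active MYC. Hdac9 stood at -2.79 and -1.83 and Lrrc10b at 1.65 and 1.64.

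With active MYC, exendin-4 moved 9 genes, 3 higher and 6 lower (882 at unadjusted p under 0.05). Lrrc10b rose by 1.64 ± 0.26 (12 against 13 arrays; adjusted p = 0.00161), Arhgef3 by 1.58 ± 0.31 and Noct, a clock-regulated nocturnin gene, by 1.41 ± 0.29. Filip1 fell by 1.98 ± 0.35, Hdac9 by 1.83 ± 0.27, Hdgfl3 by 1.04, Tirap by 0.99 and Shroom3, named after its values were seen, by 0.61, and Plppr4 was at 0.434 of its level with water. The genes past the threshold both without and with MYC were Arhgef3, Lrrc10b and Noct, higher in both (3 genes against 0.00182 for independent lists), and Filip1, Hdac9 and Shroom3, lower in both (3 genes against 0.010). The 2 effects share no arrays but use the same variance estimate of each gene, so the counts for independent lists may be too low. Their correlation across genes was 0.495 (Spearman 0.454). Without 1 array the count was 3 (MycON exendin-4 4 h replicate 2), 19 and 29 (16 h replicates 1 and 3), 20 (72 h replicate 2), 5 (MycON water 4 h replicate 2), 3 and 15 (16 h replicates 1 and 2), 4 (32 h replicate 3), 18 (72 h replicate 3) and 14 (MycOFF water 4 h replicate 3). It was 3 with all 60 arrays, 14 with quantile normalization, 48 with array weights and 21 without the 2 widest arrays. With all 60 arrays the calls of Lrrc10b, Noct, Filip1, Plppr4, Hdgfl3 and Tirap ended (adjusted p from 0.781 to 0.938), and with the replicate block those of Arhgef3, Noct, Filip1, Hdgfl3 and Tirap (from 0.0567 to 0.0863). Other probe sets of Hdgfl3, Hdac9 and Filip1 were at 0.08, -0.09 and -0.24, the mean over probe sets ended the call of Hdgfl3 (-0.38, adjusted p = 0.504), and calls of Noct, Tirap and Hdgfl3 ended without 1 of 28, 23 and 21 arrays.

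Of the lists, heat shock and immediate early genes were lower with exendin-4 in MycON islets (camera adjusted p = 0.00268; adjusted p = 0.436 with an estimated correlation), with values such as -1.02 for Fos and -0.73 for Dnajb1, and 0 of 14 members past the threshold over all genes and 2 adjusted over the list alone. Immune markers (0.00268) and stromal markers (0.00774) were higher, with adjusted p = 0.738 with an estimated correlation for both and 0 members past the threshold by either count. No list mean passed. The other 23 lists had camera adjusted p from 0.0770 to 0.978, with 0 members past the threshold over all genes. Adjusted over the list alone, 1 MYC target was lower, and 1 p53 and 1 cAMP target gene were higher. At single times 1, 1, 0, 2 and 25 genes passed in limma (772, 603, 615, 177 and 926 at unadjusted p under 0.05). Without 1 array the counts from 4 to 32 h ran from 0 to 49 (MycON exendin-4 4 h replicate 2), 0 to 5 (MycON water 8 h replicate 1), 0 to 100 (MycON exendin-4 16 h replicate 3) and 0 to 9 (MycON exendin-4 32 h replicate 2). The 25 at 72 h became 71, 9 and 15 without MycON exendin-4 72 h replicates 2 and 3 and MycON water 72 h replicate 2.

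The interaction tests whether the MYC effect differed between exendin-4 and water, and no gene passed it. In limma 0 genes passed in the average (250 at unadjusted p under 0.05), and 0 at each time (172, 309, 379, 133 and 471). Each of these unadjusted counts lay under a share of 0.05 of the 13176 genes, so they show no excess of small p. At single times the highest counts without 1 array were 2, 2, 40 (MycON exendin-4 16 h replicate 3), 3 and 28 (MycOFF water 72 h replicate 1), and testing without the filter gave 2 at 32 h and 5 at 72 h. The 5 genes with the smallest p were Ddit3 (-1.20 ± 0.29), Coa7 (1.00 ± 0.27), Fabp7 (1.28 ± 0.35), Rasd1 (0.60 ± 0.17) and Vwf (1.34 ± 0.38), each with an adjusted p of 1.00. Other probe sets of Ddit3 and Coa7 were at -0.07 and -0.15. Pdx1, which fell with MYC in water, stood at -0.29 ± 0.19 with exendin-4 (adjusted p = 0.431), and the interaction was 0.61 ± 0.27 (adjusted p = 1.00). The other probe set of Pdx1 was at -0.70 with exendin-4 and 0.22 in the interaction. Camera placed 5 lists past the threshold, and each call was lost with an estimated correlation. Immune markers (4.9e-05; adjusted p = 0.401 with an estimated correlation; mean 0.57 ± 0.34), delta and PP cell markers (0.0147; adjusted p = 0.401; mean 0.67 ± 0.32), and p53 and apoptosis genes (0.0229; adjusted p = 0.401; mean 0.26 ± 0.15) were higher. The unfolded protein response (0.0099; adjusted p = 0.507 with an estimated correlation; mean -0.20 ± 0.23) and heat shock genes (0.0229; adjusted p = 0.401; mean -0.31 ± 0.21) were lower. In these 5 lists 0 members passed over all genes, and adjusted over the list alone 1 did, in the unfolded protein response. No list mean passed, and the other 21 lists had camera adjusted p from 0.109 to 0.998, with 1 member past the threshold adjusted over the list alone, a cAMP target. The gene count was 1 without MycON exendin-4 16 h replicate 3 and 2 without MycOFF water 16 h replicate 3 or 72 h replicate 1.

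In control islets, given peanut oil and water, time alone moved 1 gene past the threshold. Prdx2, a peroxidase gene, stood at 0.78, -0.66, -3.63, 0.47 and 0.45 from 4 to 72 h (adjusted p = 0.0461), and the 16 h group held 2 arrays. The moderated F test gave 376 genes at an unadjusted p under 0.05, which is under a share of 0.05 of the 13176 genes. The count of 1 gene past the threshold became 0 when any 1 of 38 of the 52 arrays was left out and was 0 with all 60 arrays, so the call of Prdx2 was lost there. The count was 46 without MycOFF water 72 h replicate 1 and 11 without MycOFF water 16 h replicate 3. Values of Nid2, Insm2, Igsf11, Cep135, Aox1, Zfp784, Mtif3, Gask1b and Rab39 had the next smallest p and did not pass (adjusted p from 0.0883 to 0.577). No list mean changed over time in these islets (adjusted p from 0.799 to 0.999).

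Islet hormone genes were not shown to change. Ins2 differed by 0.13 ± 0.99 with MYC in water and 0.06 ± 0.95 with exendin-4, and its value in the arrays kept ran from -7.15 to 0.95, so that a change of several log2 units would not have been detectable. Iapp (-0.17 ± 0.43), Gcg (-0.16 ± 0.16), Sst (-0.48 ± 0.63) and the glucose transporter gene Slc2a2 (-0.61 ± 0.24, adjusted p = 0.144) did not pass with MYC in water, and with exendin-4 they stood at 0.33, 0.22, 0.82 and -0.58. The ornithine decarboxylase gene Odc1, a known MYC target, was at 0.83 ± 0.26 (adjusted p = 0.0504) in water and rose by 0.84 ± 0.25 (adjusted p = 0.0387) with exendin-4. Mki67 was at 1.75 (adjusted p = 0.0503) and 1.53 (0.0790), Cdkn1a at 0.73 and 1.26, Ncl at 0.62 and 1.28 and Ccnd2 at 0.44 and 0.49, and none of these passed. Cdkn2a was at 0.52 (adjusted p = 0.109) in water, Irs2 at -0.36 and -0.38, Cpa1 at 0.44 and 0.36, Ptprc at 0.12 and 0.70 and Esr1 at -0.53 and -0.27. Without MYC exendin-4 left Ins2 at 0.46 ± 0.95, Slc2a2 at -0.68 ± 0.23 (adjusted p = 0.323) and Irs2, a CREB target, at 0.57 ± 0.25 (adjusted p = 0.580), and none of the other fixed genes passed for exendin-4 in either state of MYC. Myc and Glp1r were under the filter and not tested, and Ins1 and Mafa were not analysed here.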

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

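The tests on the left-out arrays, and their division into 7 arrays and 1 array, were chosen after the result was seen, as were the F test over both injections, the contrast of times with its cell marker covariates, the list means and, for immune markers, the comparisons with T lymphocyte markers and with each single list and those without a MycOFF array.

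The MYC effect differed between times for the replication list (adjusted p = 0.0231) and the mitosis list (adjusted p = 0.00231), and for 209 genes over both injections and 3 genes with water. Of 100 orders with times shuffled within each treatment, 1, the real one, gave as many as 209 genes (highest other 36). This share lies under 0.05, so chance is an unlikely source of that count. The count was 18 with all 60 arrays and 84 with the replicate block.

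A pattern in these changes was a MYC response that was high at 4, 8 and 32 h and low at 16 and 72 h, or the reverse. In the contrast of these times over both injections 556 genes passed, 262 high at 4, 8 and 32 h and 294 high at 16 and 72 h, against 158 for the next best of the 10 ways to part the times, and 1 of 100 shuffled orders gave as many (highest other 156). Of 45 genes chosen with water, 45 had the same sign with exendin-4, with a median contrast of 1.27. The median was 1.12 in MycON and -0.141 in MycOFF exendin-4 arrays, which argues against a change in the MycOFF arrays alone as its source. These genes were chosen on MycON minus MycOFF. An effect of time of day alike in both cancels there, so these genes cannot test such an effect. The median contrast was 1.26 with 3' minus 5' differences as covariates, which argues against RNA quality. It was 1.34 with immune and alpha cell marker means as covariates, which argues against the share of these cells for these 45. With 4-hydroxytamoxifen given once a day, the hours since the last dose may set this response, as a hypothesis that was not tested. Mitosis genes were higher at 16 and 72 h in this contrast (list mean -1.98, adjusted p = 6.2e-04 in limma). What part the cell cycle has in the pattern was not tested. A clock phase that acts only with MYC stays open, since dose and time of day run together, as does cell content for others of the 556, since immune (-1.08, adjusted p = 0.0356) and alpha cell markers (-0.69, adjusted p = 0.0400) moved in this contrast and 233 of the 556 passed with these covariates.

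Camera placed 5 lists past the threshold for the interaction of MYC and exendin-4: delta and PP cell markers (0.0147), immune markers (4.9e-05), p53 and apoptosis genes (0.0229), the unfolded protein response (0.0099) and heat shock genes (0.0229). None of these passed with an estimated correlation, and of 100 random splits 56 gave as many lists (real 5, median other 5, highest other 13), so chance is not excluded.

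Immune markers rose with MYC at 72 h under exendin-4, by 2.21, with Cd68 at 5.12, C1qb at 4.26, C1qc at 3.61, Lyz2 at 3.51 and Cd14 at -0.21. Lymphoid tissue captured with the islets as the whole source is argued against by a macrophage mean (7 of its 10 genes are also in a fixed list) 3.05 ± 0.54 (SE) above the B lymphocyte mean, 2.81 ± 0.61 without MycOFF exendin-4 72 h replicate 2, and 1.87 ± 0.53 above the T lymphocyte mean; B lymphocyte markers stood at -0.68 ± 0.25, -0.12 ± 0.18 without that array, while T lymphocyte markers stood at 0.51 ± 0.14, so a small lymphocyte part stays open. A single array is argued against by an immune mean of 2.00 or more without each of the 6 arrays of the MycON and MycOFF groups. A loss of islet cells that raises every other type alike is argued against by an immune mean 1.65 ± 0.45 (SE) above that of 4 other lists. The immune mean lay 1.79 ± 0.51, 1.61 ± 0.47 and 2.32 ± 0.91 above endothelial, duct and acinar markers. It lay 0.88 ± 0.53 above stromal markers, and 0.21 ± 0.54 above them without MycOFF exendin-4 72 h replicate 2. Stromal markers stood at 1.33 ± 0.56, and at 2.16 ± 0.55 without that array. A rise of immune markers beyond that of stromal markers was thus not shown. More macrophages in or at MycON islets, or a change in the macrophages there, may underlie the rise of immune markers, as a hypothesis, while stromal tissue with macrophages captured with the islets stays open and a dependence on exendin-4 was not shown.

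The 8 arrays left out by the submitters enter no comparison, and 7 of them held a signal above every array kept. T lymphocyte markers averaged 7.03 in MycON exendin-4 4 h replicate 3 (highest array kept 0.66), with B lymphocyte markers at 5.78. In MycON exendin-4 16 h replicate 2 and 32 h replicate 3 and MycON water 16 h replicate 3, epidermis markers averaged 8.91, 8.97 and 8.68 (highest kept 1.72) and skeletal muscle markers 9.75, 10.4 and 10.2 (highest kept 3.15). B lymphocyte markers averaged 8.11, 7.56 and 7.18 in MycOFF water 8 h replicate 2, 16 h replicate 1 and 72 h replicate 2 (highest kept 1.95), with T lymphocyte markers at 5.50, 4.76 and 3.62.

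Other tissue captured in place of islets is a candidate explanation for these 7 arrays: 7 had such a list above and the beta cell list below all arrays kept (-1.02). The 3 with epidermis and muscle signal correlated at 0.919 to 0.968 and the 4 with lymphocyte signal at 0.763 to 0.873. In MycON water 32 h replicate 1 the highest such list, skeletal muscle, lay at -0.118 from the highest array kept and the beta cell list at -1.04, below all arrays kept, so captured tissue stays open there. Degraded RNA as the source for all 8 is argued against by 7 of the 8 arrays with both 3' minus 5' differences at or below the highest array kept. In MycOFF water 72 h replicate 2 the beta-actin difference was 1.67, above the highest array kept (1.03), so degraded RNA stays open there. The bar is the highest of 52 arrays, so RNA degraded in part is not excluded for the others. No biological explanation was tested.

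Other splits of the arrays were tested for each count. For MYC with water, 1 of 100 splits gave as many genes (real 737, highest other 3), and with exendin-4 1 of 100 (real 763, highest other 393). The real split is counted among the 100. Both shares lie under 0.05, so chance is an unlikely source of these counts. For lists past camera, 7 of 100 gave as many with water (real 11, highest other 13) and 5 of 100 with exendin-4 (real 12, highest other 15), so chance is not excluded. The median of the other splits was 6 lists in each. For list means, 2 of 100 did in each (real 5, highest other 5, and real 7, highest other 7). This share lies under 0.05, but another split reached the real count in each, so chance is unlikely but not excluded.

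For exendin-4 without MYC, 4 of 100 splits gave as many genes (real 30), under the share of 0.05, but the highest other split gave 889, which points to a structure of the samples that was not tested. With MYC, 1 of 100 did (real 9, highest other 6), so chance is an unlikely source of that count. For lists past camera 94 and 78 of 100 gave as many for exendin-4 without and with MYC (real 1 and 3, highest other 14 and 13). The real counts lay under the medians of the other splits, 5 and 4. Chance is not excluded for these lists. A real count of 0 is reached by any split, so 100 of 100 says nothing about the genes of the interaction (highest other 201, which also points to a structure of the samples) or, at 100, 100 and 100, about list means for exendin-4 without MYC, with MYC and the interaction (highest others 7, 4 and 2).

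At single times, groups of 3 against 3 allow 10 splits, too few for a share under 0.05. As many genes came from 1 split for MYC with water at 4 h (real 99, highest other 6), 1 for MYC with exendin-4 at 8 h (real 179, highest other 2) and 3 at 72 h (real 132, highest other 237). For exendin-4 without MYC it was 2 at 4 h (real 1, highest other 1) and 10 at 32 h (real 0, highest other 3), and with MYC 3 at 8 h (real 1, highest other 2) and 2 at 72 h (real 25, highest other 29).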

How the results depend on the processing

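The alternatives planned before are given first, and the filter at the 60th percentile, the array weights, the fit without the 2 widest arrays and the acinar covariate were chosen after seeing the data, as were the test of change over time on both injections and its alternatives. Of 270 counts of genes or lists under another setting, 145 lay within 1.5 times the reported count and 125 did not. Of 1827 values of named genes, 1590 kept direction and side of the threshold, 138 that had passed did not pass, 16 passed newly, 1 called value turned its sign, and 82 values not past the threshold changed sign. The cause of a difference was not tested except where the setting itself changes the number of genes or arrays. The number of arrays limits the precision, and what signal over background limits was not measured, since the values do not hold it.

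All 60 arrays, in limma, gave 175 genes for the MYC effect with water in the average, of which 161 were among the 737, and 11, 7, 1, 10 and 0 from 4 to 72 h. For MYC with exendin-4 they gave 0, 24, 0, 6 and 11 from 4 to 72 h. The exendin-4 effect without MYC had 8 genes in the average, 0 at 4 h and 1 at 16 h, and the one with MYC had 3 in the average, 0 at 4, 8 and 32 h and 2 at 72 h. Changes over time were 0 with water, 0 in control islets and 18 over both injections. Lists past camera were 5 and 12 for exendin-4 without and with MYC and 10 for the interaction. Xbp1 turned from a fall to 0.22 (adjusted p = 0.818), the 1 reversed value.

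Testing without a filter, which adds genes, gave 7 genes for MYC with water at 72 h. For exendin-4 without MYC it gave 17 in the average and 2, 3, 1 and 2 at 4, 8, 32 and 72 h, and with MYC 21, 11 and 11 at 4, 16 and 32 h. The interaction had 2 genes at 32 h and 5 at 72 h, and changes over time were 7 with water and 8 in control islets.

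Quantile normalization gave 1175 genes for MYC with water in the average, and 236, 115, 28 and 228 at 4, 8, 16 and 32 h. The splits into higher and lower were 184 and 52 at 4 h, 81 and 34 at 8 h and 164 and 64 at 32 h, against 92 and 7, 28 and 5, and 53 and 10. MYC with exendin-4 had 57, 323, 1, 241 and 83 genes from 4 to 72 h. Its splits were 51 and 6 at 4 h, 255 and 68 at 8 h and 169 and 72 at 32 h, against 19 and 6, 165 and 14, and 37 and 6, and in the average the share of higher genes was 67.9% against 78.8%. Exendin-4 without MYC had 51 in the average and 4, 6, 3 and 0 at 4, 8, 16 and 72 h, with 1 higher and 2 lower at 16 h against 3 and 2. With MYC it had 14 in the average, 6 at 32 h (2 higher and 4 lower, against 0 and 2) and 6 at 72 h (5 and 1, against 24 and 1). Changes over time were 10 with water, 5 in control islets and 375 over both injections, and lists were 2 for exendin-4 without MYC and 3 for the interaction.

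With the replicate block, MYC with water had 15, 19, 25 and 0 genes at 8, 16, 32 and 72 h and MYC with exendin-4 12, 119, 7 and 27 at 4, 8, 16 and 32 h. Exendin-4 without MYC had 13 in the average and 0 at 16 h, and with MYC 2, 0, 1 and 0 at 4, 8, 16 and 32 h. Changes over time under the block were 0 with water and 84 over both injections, and 5 lists passed for exendin-4 with MYC. The block gave no value for the time course in control islets. The replicate numbers did not pair the arrays: arrays of 1 number had a mean correlation of -0.027 over 66 pairs (15 above 0.1), against 0.013 over 136 pairs of other numbers, and 14 of 52 arrays correlated best with their own number.

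Taking the mean over probe sets gave 162, 70, 95 and 0 genes for MYC with water at 4, 8, 32 and 72 h and 17 for MYC with exendin-4 at 16 h. Exendin-4 without MYC had 49 in the average and 2, 1 and 0 at 4, 16 and 72 h, and with MYC 2, 0, 2 and 4 at 4, 8, 16 and 32 h. The interaction at 72 h had 4. Changes over time were 5 with water, 0 in control islets and 327 over both injections, and 2 lists passed for exendin-4 without MYC. With an estimated correlation, lists past camera were 1 and 1 for MYC with water and with exendin-4, and 0, 0 and 0 for exendin-4 without MYC, with MYC and the interaction.

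A fit of only the groups compared used fewer arrays, and for single times it held all 4 treatments of that time. It gave 60, 20, 0, 99 and 0 genes for MYC with water from 4 to 72 h. For MYC with exendin-4 it gave 11, 84, 0 and 3 at 4, 8, 16 and 72 h. Exendin-4 without MYC had 11 in the average and 0, 2, 0 and 0 at 4, 8, 16 and 72 h, with MYC 0, 0 and 1 at 4, 32 and 72 h, and the interaction 2 at 8 h. Array weights gave 48 genes for exendin-4 with MYC and 380 for the change over time over both injections. Without the 2 widest arrays, exendin-4 with MYC had 21 genes, and lists were 3 for exendin-4 without MYC and 8 for the interaction. The filter at the 60th percentile gave 2 lists for exendin-4 without MYC. With the acinar covariate every averaged count lay within 1.5 times, at 700, 738, 32, 9 and 0 genes.

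Leaving out each of the 52 arrays in turn kept the average between 493 and 841 genes for MYC with water and between 508 and 924 for MYC with exendin-4. A group of 2 then holds a lone array, which is assumed to vary like the other groups. The range was 11 to 45 for exendin-4 without MYC, 3 to 29 with MYC, and 0 to 2 for the interaction. At single times MYC with water ranged from 41 (without MycOFF water 4 h replicate 1) to 127, from 4 (MycOFF water 8 h replicate 3) to 57, from 2 to 194 (MycON water 16 h replicates 1 and 2), from 20 (MycON water 32 h replicate 3) to 78 and from 0 to 125 (MycOFF water 72 h replicate 1). MYC with exendin-4 ranged from 8 to 50 (MycOFF exendin-4 4 h replicates 2 and 1), 57 to 257, 3 to 143 (MycOFF and MycON exendin-4 16 h replicate 3), 12 (MycOFF exendin-4 32 h replicate 1) to 52, and 50 to 238. Exendin-4 without MYC ranged from 0 to 3, 0 to 8, 2 to 23 (MycOFF water 16 h replicate 3), 0 to 0 and 0 to 112 (MycOFF water 72 h replicate 1). With MYC it ranged from 0 to 49 (MycON exendin-4 4 h replicate 2), 0 to 5, 0 to 100 (16 h replicate 3), 0 to 9 and 9 to 71. The interaction ranged from 0 to 2, 0 to 2, 0 to 40 (MycON exendin-4 16 h replicate 3), 0 to 3 and 0 to 28 (MycOFF water 72 h replicate 1). Changes over time ranged from 0 to 31 with water, 0 to 46 in control islets and 161 to 310 over both injections. Lists past camera ranged from 9 to 12 and 8 to 14 for MYC with water and with exendin-4, 0 to 3 and 2 to 7 for exendin-4 without and with MYC, and 1 to 10 for the interaction. Of 9516 values of named genes with 1 array left out, 8936 kept direction and side of the threshold, 366 that had passed did not pass, 35 passed newly, 179 values not past the threshold changed sign, and 0 called values reversed.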

Other observations

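The contrast of 4, 8 and 32 h against 16 and 72 h and the values here were chosen after seeing the data. Among genes not described so far, Wdr75 and Zmynd19 stood at 0.95 and 2.75 at 4 h and at -0.25 and 0.46 at 16 h in the MYC effect over both injections, and the mitosis genes Ube2c and Ccnb2 at -0.72 and -0.45 at 4 h and 3.01 and 3.13 at 16 h. Of the 26 list means, 4 passed for this contrast, each with higher values at 16 and 72 h: mitosis (-1.98, adjusted p = 6.2e-04), immune markers (-1.08, adjusted p = 0.0356), cAMP and CREB targets (-0.51, adjusted p = 0.0356) and alpha cell markers (-0.69, adjusted p = 0.0400). Ribosome biogenesis was at 0.68 and did not pass (adjusted p = 0.0733). In MycON arrays alone 1395 genes passed the contrast, and in MycOFF arrays alone 1 gene did.

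Among the arrays kept, single genes of other tissues reached high values in single arrays: Ighm of B lineage cells up to 9.33 and Acta1 of skeletal muscle up to 4.93 above their medians.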
